A study of Mus musculus with 2 samples.

How the data were processed

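RNA of the microdissected subventricular zone from 300 µm brain sections was labelled with biotin and hybridised to membrane arrays, starting from 1 µg of total RNA, per the labels. Film densities were measured in GEArray Expression Analysis Suite 2.0, per the labels. The deposited workbook gives for each of 288 spots an intensity, which is the average density of the spot, and an intensity of the local background, per the file headers. It also gives a report signal per array, a ratio of lysolecithin over NaCl, a present or absent call with a threshold of 1.5, and a bleeding call, per the file headers. Bleeding was marked at 15 spots of the NaCl array and 22 of the lysolecithin array. The deposited value table gives a signal for 128 spots, which per the labels is the density divided by the mean of Gapdh, Ppia and beta-actin; its scale is not stated beside it. The median of that table was 1.02 for the NaCl array and 0.915 for the lysolecithin array.

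The workbook header names another array and project than the labels, so the source of its RNA remains open. The report signals were compared with the densities. For 280 of 288 spots they equalled the density minus the array's lowest density, divided by 1 constant per array (4295 and 4250), within 1e-06. The other 8 genes departed in 13 cells. For this reason the folds were computed from the densities, and the deposited signals are an alternative.

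For the main values the lowest density of each array (7301 for NaCl, 8256 for lysolecithin) was subtracted, and the result was divided by the mean of Gapdh and Ppia. The design names beta-actin too, but no such spot was found on the workbook's array, so 2 control genes were used and scaling by beta-actin alone was not run. This scaling rests mostly on saturated spots. The first and second spots of Gapdh and of Ppia were near the film's ceiling on both arrays. The third Ppia spot was at 56207 on the NaCl array, just under the cut of 57331 for near the ceiling, and at 60012 on the lysolecithin array. The only Gapdh spot well below the ceiling had a log2 ratio of -0.63. A difference in total signal between the arrays can therefore be missed, and every fold depends on this scaling. Folds were taken for genes called present on both arrays. A gene present on 1 array was given as the bright value over the higher of its own dim value and the lowest value of a present gene on the dim array, leaving out the 8 genes, a choice made after seeing the data; no bound is given where this is under 1. Spots at or above 0.95 of the highest density, leaving out the single highest, were taken as near the ceiling. The number of arrays limits the precision, and no p-value was computed.

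Before the data were examined, 16 gene lists, the thresholds of 1.5-fold and 2-fold, and the rule for named genes were fixed. The rule takes up to 12 genes per direction that pass 1.5-fold, up to 5 per direction present on 1 array, each present neurotrophin and EGF-neuregulin gene, and the control genes. At 2-fold, 3 genes were higher and 1 was lower. Other genes named are members of fixed lists or lie beside a named spot, and were chosen after their values were seen. A list with at least 3 members present on either array was given its median log2 ratio and its percentile among 10000 random lists matched in 3 bins of level, as a description of these arrays. Genes present on 1 array entered these medians and the random lists with their plain log2 ratio, not with a bound. Of 263 genes, 253 were matched by accession to the RefSeq gene table of assembly GRCm38.p6, and 14 have a new symbol there; array symbols are kept and no coordinates are given.

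The arithmetic was checked on 2 copies of the NaCl array. Of 49 genes present on both arrays, 10 were raised and 10 lowered by exactly 2-fold in 1 copy. All of these, 10 and 10, were recovered with no other gene called. No noise, film ceiling or local background was added, so this outcome was fixed in advance and says nothing about accuracy on these films. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The alternatives were other scalings, backgrounds and filters, 14 for the fold results. Subtracting the lowest spot density, counted among these, repeats the main setting.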

Results

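Gene expression in the subventricular zone, the neurogenic layer lining the lateral ventricle, was compared in mice 4 days after an injection into the corpus callosum of either lysolecithin, a lipid that strips myelin from axons, or NaCl as the vehicle. The labels give 1 sample per group, taken at postnatal day 60. Each sample was hybridised to 1 membrane array, on which the darkness of each gene's spot on a scanned film is the measurement. With 1 array per group there are no replicates, so no difference below has a test or a replicate check. Values are given as lysolecithin over NaCl, and "higher" and "lower" describe these 2 arrays.

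The gene names come from a deposited workbook whose header does not match the labels. The labels describe an array of 113 neurotrophic signalling genes, whereas the workbook is headed as a neurogenesis and neural stem cell array, and its project name refers to neural stem cells and to day 5. The workbook's arrays are named WT Nacl and WT Lyso, and they were assigned to the groups by the NaCl and lysolecithin parts of those names. The sample titles do not carry the tag WT. Whether they hold the RNA that the labels describe was not settled, and this limit applies to every named gene. A second deposited table holds 128 numbered spots without names.

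On the workbook's arrays, 263 genes other than controls were measured. The authors called 58 of the 263 genes present on the NaCl array, 22.1% (95% Clopper-Pearson interval 17.2 to 27.6%). On the lysolecithin array they called 55 present, 20.9% (16.2 to 26.3%). These intervals cover counting error only. Altogether 49 genes were present on both arrays, 9 on the NaCl array only, 6 on the lysolecithin array only and 199 on neither. Both blank spots were dark, with a mean density of 27674 on the NaCl array and 26757 on the lysolecithin array, and 26 of the 263 genes exceeded the blank mean on both. The blanks lie beside saturated control spots and were paler than the film around them, so they do not measure the background elsewhere.

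Among the 49 genes present on both arrays, 6 were at least 1.5-fold higher after lysolecithin and 3 were at least 1.5-fold lower, while 40 lay within 1.5-fold. Only 22 of the 49 exceeded the blank mean on both arrays, and 7 of the 9 genes past 1.5-fold, all but Chrd and Fgf2, did not. Igf1, which encodes a growth factor, had 3.47 times its NaCl value, and Vegfa, an angiogenic growth factor, 2.47 times. Their NaCl spots were dimmer than any other present gene, and against the lowest other present gene they were at least 1.42-fold and 1.40-fold higher, under the 1.5-fold threshold. Their log2 ratios were 0.87 and 0.70 without background subtraction and 3.47 and 4.47 with local background subtracted. The last 2 rest on NaCl spots only 737 (Igf1) and 268 (Vegfa) units over local background. Across 249 other genes the change of this excess between the arrays had an SD of 2317, so these 2 sizes are not reliable. Dlg4, which encodes a scaffold protein of excitatory synapses, was 3.23-fold higher. Dcamkl1, now named Dclk1, a microtubule-associated kinase of developing neurons, was 1.95-fold higher, and Gfra2, a receptor for GDNF family ligands, was 1.66-fold higher, but under 1.5-fold, at log2 ratios of 0.47 and 0.55, with medians set equal and without background subtraction. Bmp4, a bone morphogenetic protein, had a log2 ratio of -1.44, but its lysolecithin spot was dimmer than any other present gene, and on that floor it was at least 1.57-fold brighter on the NaCl array. Without background subtraction its log2 ratio was -0.64, and with local background subtracted -4.36. The latter rests on a lysolecithin spot only 531 units over local background, so its size is not reliable either. The log2 ratios of Fgf2, a fibroblast growth factor, and of Pard3, a cell polarity protein, were -0.62 and -0.59. The NaCl spot of Fgf2, at 56943, was close to the film's ceiling, so its difference is compressed, and its log2 ratio was -1.22 with the blank mean and -1.77 with local background subtracted. Fgf2 and Pard3 were within 1.5-fold with Gapdh alone (-0.53 and -0.50) and without background subtraction (-0.51 and -0.29).

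Of these 9 genes, Igf1, Vegfa, Chrd and Bmp4 have deposited report values that do not follow from their spot densities, and without such genes the counts were 3 higher and 2 lower. Chrd, a BMP antagonist, is counted among the 6 higher genes, but its density was 57990 on the NaCl array, near the ceiling of the film, and 88903 on the lysolecithin array, where the highest density of any other spot was 60307. No fold or direction is given for it. Dlg4 and Dcamkl1 lie in an area of the lysolecithin array where the film around the spots was darker too, and with the local background subtracted their log2 ratios were -0.027 and -0.81. The changes behind these 2 ratios were -338.3 and -680.4 units, within the SD of 2317, so neither shows a direction. The split between higher and lower genes also moved with scaling. With the median of the genes present on both arrays set equal it was 4 higher and 11 lower, and the median log2 ratio moved from 0.04 to -0.23. With Gapdh alone it was 8 and 1.

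**Figure D1:**
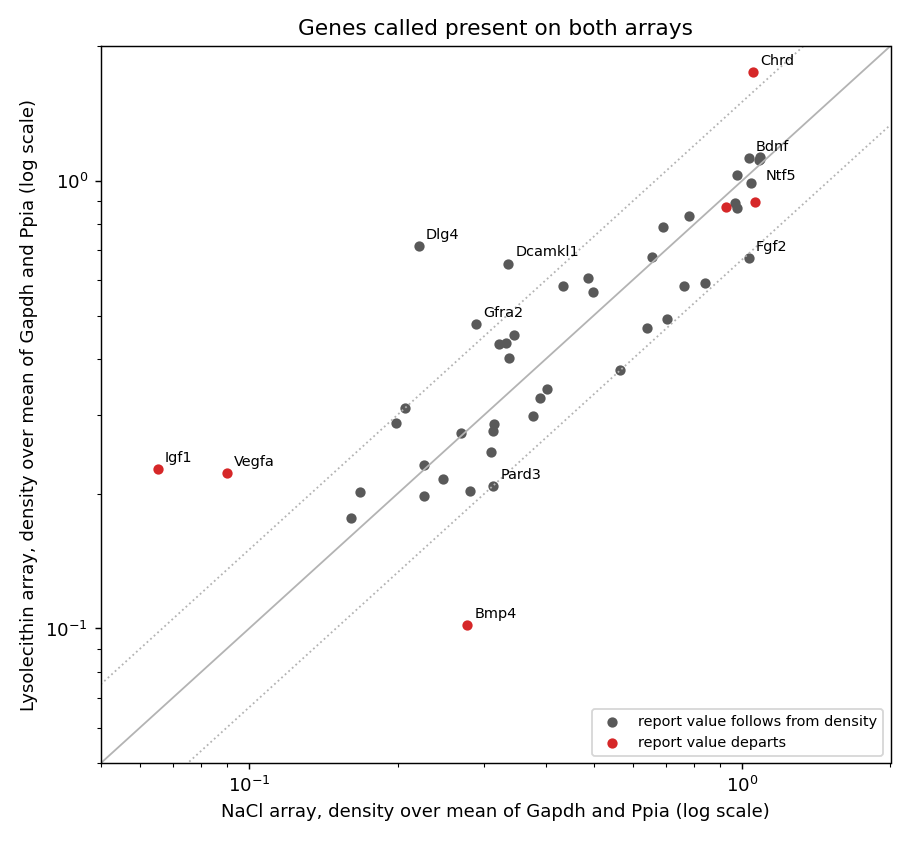
Normalized density of each gene present on both arrays, NaCl array (x axis) against lysolecithin array (y axis), both on log scales; the solid line marks equality and the dotted lines 1.5-fold. Red points are genes whose report values depart from their densities; Igf1, Vegfa, Chrd and Bmp4 are among the 9 genes outside or on the dotted lines.

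The growth factor and BMP list had 7 genes on the array, of which 4 were present, namely Igf1, Vegfa, Chrd and Bmp4. Its median log2 ratio was 1.02, at percentile 98.5 among 10000 random lists of like level, but this median is the mean of Vegfa and Chrd, and Chrd has no usable value. All 4 present members have report values that depart from their densities, so no direction is given for the list. Deposited records give other sizes for the same genes. In the authors' deposited table the ratio was 1.90 for Igf1, 2.69 for Vegfa and 0.686 for Bmp4, against 3.36, 2.39 and 0.356 from the densities on the scale of that table. For Ntn1 and Numb, which also depart, the direction differed too. Their deposited ratios were 1.42 and 1.20, against 0.817 and 0.911 from the densities. Nog departs as well, with 1.87 against 0.907, but it was called absent and lay below local background on both arrays. Before subtraction its density was 9197 on the NaCl array and 9957 on the lysolecithin array, so no direction is given for it. The deposited ratios of Igf1, Ntn1 and Numb also differ from those of their own report values, 1.81, 1.41 and 1.30.

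The GDNF family had 6 genes on the array. Gfra2 had a log2 ratio of 0.73, Gfra3 had a log2 ratio of 0.58 and Gdnf of -0.25, while Gfra1 was present on the NaCl array only. The median of these 4 genes was 0.17, at percentile 68.7 of matched random lists, and 0.58 without Gfra1. With Gfra1 taken as unchanged, since it has no usable bound, the median was 0.29. The sign of the median of 0.17 turned with scaling, to -0.098 with the median of the genes present on both arrays set equal. Among neurotrophins and their receptors, 2 of 6 genes were present. Bdnf had a log2 ratio of 0.12 and Ntf5 of 0.04, and both spots were close to the film's ceiling, which compresses differences. With local background subtracted their log2 ratios were -1.71 and 1.00, so no direction is given for either. All 4 EGF-neuregulin genes on the array, Nrg1, Erbb2, Erbb3 and Erbb4, were called absent on both arrays.

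Of 20 genes for neurite growth, guidance and neurogenesis, 5 were present on both arrays and none of the 5 passed 1.5-fold. Nes, the intermediate filament of neural progenitors, had a log2 ratio of 0.43, and Stmn1, a microtubule-destabilising protein, of -0.16. Dcx, also of this list, was present on the lysolecithin array only (its bound is given with the other genes of that kind). The median of these 6 genes was -0.043, at percentile 46.2, and -0.16 without Dcx. Its sign turned between settings, from -0.31 with the median of the genes present on both arrays set equal to 0.20 with the authors' report values, and it was 0.077 without Ntn1, a present member whose report value departs, so no direction is given for the list. Of 4 oligodendrocyte lineage genes only Olig1 was present, with a log2 ratio of 0.32. The astrocyte marker S100b was present on the NaCl array only, with densities of 14958 on the NaCl array and 15017 on the lysolecithin array, so no fold is given. The 2 genes on the array from each of the immune, apoptosis and immediate-early lists were called absent on both arrays. One of them, Zfp91, was near the film's ceiling on both arrays, at 60205 and 59484. The film around it was as dark, so its absent call does not show a lack of signal. Bcl2l1 went from 11720 to 20140, with darker film around it on both arrays, at 14677 and 22019. No gene of the CNTF, heat shock or endothelial lists was on the array. No neuron marker was matched by symbol, but Mtap2, an older symbol of the listed Map2, was on the array and called absent on both arrays.

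Genes present on 1 array have only bounds. On the lysolecithin array, Efnb1, an ephrin ligand, was at least 4.95-fold higher, and Dcx, a microtubule-associated protein of migrating neuroblasts, at least 4.70-fold higher. These bounds were 3.04 and 2.92 without background subtraction and 7.88 and 6.07 with local background subtracted. Both lie in the darker area of film, where the local background around Dcx went from 11568 to 37465. Zic2, a transcription factor, was at least 2.57-fold higher, and at least 1.75-fold with local background subtracted. The film around it was darker as well, at 25537 against 15912, and the 2 control spots beside it, both called absent on the NaCl array, had densities of 16778 and 16135 against 9527 and 10014. Acsl6 was at least 1.57-fold and Fezf2 at least 1.21-fold. Their NaCl spots, called absent, had densities of 28071 and 46228, with the film around them darker at 31161 and 50012. Fezf2 was marked as bleeding on both arrays and lies between spots near the ceiling. On the NaCl array, Apbb1 was brighter by at least 1.76-fold, Apaf1 by at least 1.35-fold, Efnb3 by at least 1.30-fold, Galr2 by at least 1.21-fold and Cables1 by at least 1.16-fold. Without background subtraction the bound of Apbb1 was 1.33. With local background subtracted the bounds were 8.94 for Apbb1, 5.49 for Apaf1, 2.15 for Efnb3, 3.03 for Galr2 and 1.96 for Cables1, and 4.07 for Acsl6. Those of Apbb1, Apaf1 and Cables1 rest on a floor of 461 units over local background (Wwp1, lysolecithin array). Those of Acsl6, Efnb1, Dcx and Zic2 rest on 905 units (Atoh1, NaCl array). Both floors lie below the SD of 2317 given above, so these sizes are not reliable. With the blank mean subtracted the bound of Acsl6 was 32.0, because its NaCl spot, at 28071, barely exceeded the blank mean of 27674.

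**Figure D2:**
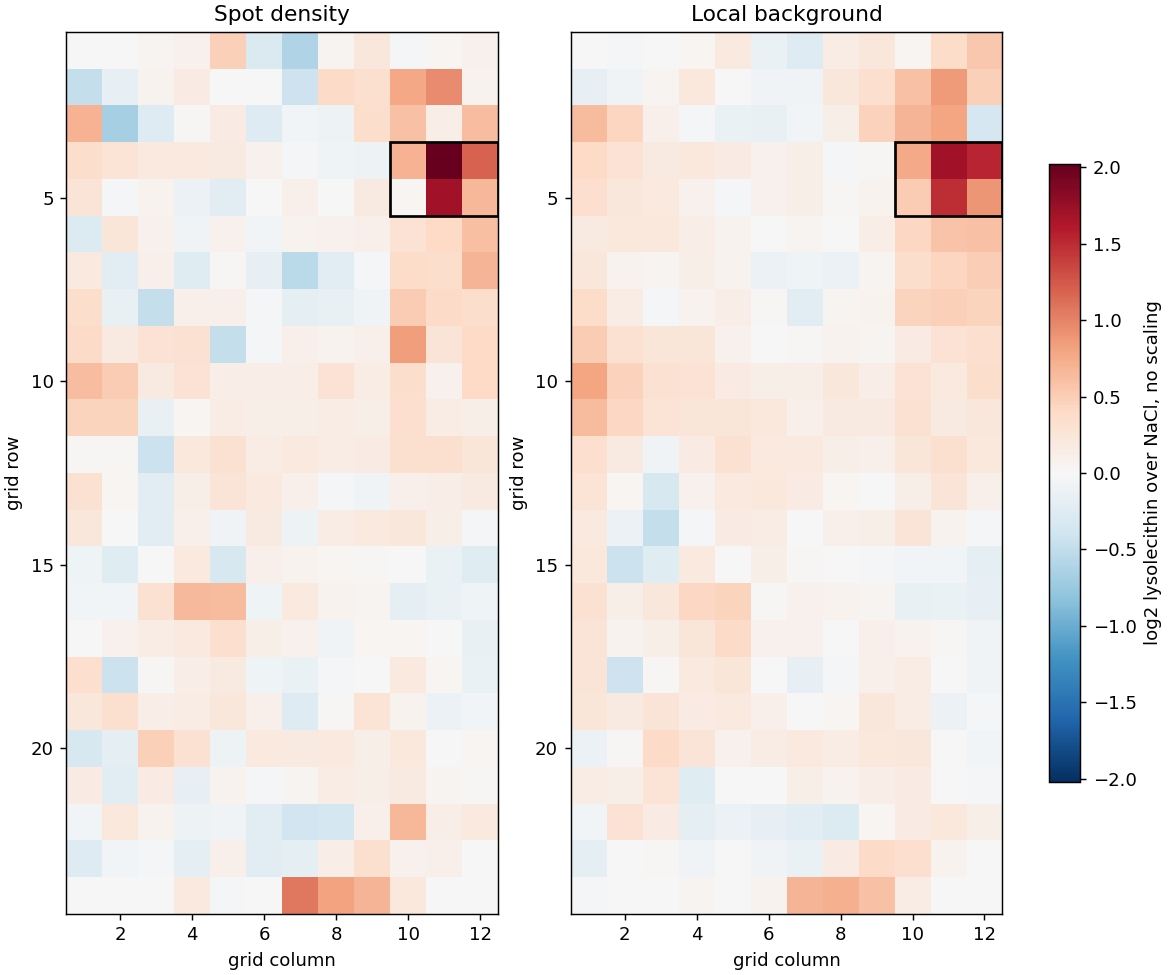
Log2 ratio of lysolecithin over NaCl at each place of the grid of 24 rows and 12 columns, for spot density (left) and for the film around each spot (right), without scaling. The box holds Dcamkl1, Dcx, Dlg4, Efna5, Efnb1 and Efnb2; the local background log2 ratio was 1.70 around Dcx.

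Repeated control spots gave a rough view of the technical spread. The first and second Gapdh spots were at the ceiling, and the 3 Ppia spots lay between 56207 and 60012, close to it. The third Gapdh spot, below it, went from 38938 to 27794 and was called absent on the lysolecithin array. After subtraction of the lowest density and scaling, its log2 ratio was -0.63. The first B2m spot, also well below the ceiling and called absent on both arrays, had a log2 ratio of -0.40. The SD of the log2 ratio between repeated spots of Gapdh, Ppia and B2m was 0.27 over 9 spots, but 6 of the 9 were near the ceiling on both arrays, so this value understates the spread of unsaturated spots.

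In the table of 128 unnamed spots, 124 had values above 0 on both arrays. Of these, 33 were at least 1.5-fold higher after lysolecithin and 16 at least 1.5-fold lower, and the median log2 ratio was -0.02. Spots 17 and 96 had the highest lysolecithin values, at 5.59 and 5.73, against NaCl values of 1.13 and 1.44. With only spots of at least 0.5 on 1 array, the counts were 21 and 7.

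**Figure D3:**
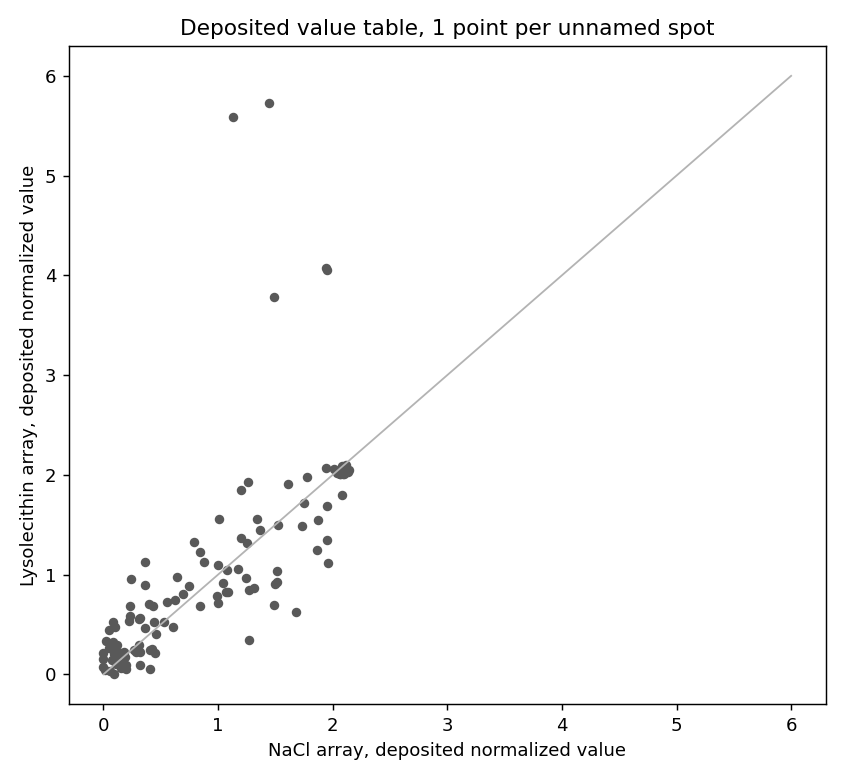
Deposited normalized value of each of the 128 unnamed spots on the NaCl array (x axis) and the lysolecithin array (y axis), with the line of equality. On the lysolecithin array 5 spots lie between 3.78 and 5.73, and the next highest value is 2.10.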

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

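All tests in this part were chosen after the results were seen.

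The report values of 8 genes (Bmp4, Chrd, Dll1, Igf1, Nog, Ntn1, Numb and Vegfa) did not follow from their densities, which stood out because the other 280 spots followed 1 relation. The departures covered 5 cells of the NaCl array and 8 of the lysolecithin array. No biological explanation was tested, since a change of RNA moves a density and the value computed from it alike. Numb and Ntn1 exceeded the computed value by 4 and 7. Of the departing cells, 5 (Bmp4 and Dll1 on both arrays, Chrd on the lysolecithin array) share their first 10 decimals with a cell of Atoh1 or Dlg4, 4 of them with another whole number, which 0 of 561 other cells do. None (0) of the 55 other cells with a reset spot area departed, which argues against a different calculation for reset spots. Of the 13 departing cells 12 had 15 or fewer digits, against 35 of 563 other cells; a candidate explanation is that they were entered separately from the software's calculation, and how or why this happened is not known. Igf1 and Vegfa were called present on the NaCl array at 10441 and 11638, below the lowest other present gene at 14958, and Bmp4 on the lysolecithin array at 12950, below 16390.

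Neighbouring spots around Dcx were brighter on the lysolecithin array, and the film around them was too, with a log2 local background ratio of 1.70 at Dcx. Over local background, the densities of Dcamkl1, Dlg4 and Efnb2 differed by -680.4, -338.3 and -2363, where single genes elsewhere had an SD of 2317 over 249 genes. Efnb2 was below its local background and called absent on both arrays, so more RNA of these 3 genes is neither shown nor excluded. Dcx and Efnb1 differed by at least 6280 units, so more RNA of these genes remains possible. A bright patch of film may have raised spots and surroundings alike: the median local background over density was 0.876 in the 4 patch spots between 30000 and 50000, against 0.640 in 19 spots of like density elsewhere. However, 5 of those 19 exceeded the patch median, where the test allowed at most 1 in 10. These 5 (Acsl6, Atoh1, Wwp1, PUC18 and AS1R1) each lie beside a spot near the ceiling, which may darken the film around them. Dlg4 of the patch also lies beside such a spot, Chrd. The comparison therefore cannot judge the patch, and a patch and more RNA of these genes cannot be told apart.

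Among the unnamed spots, 5 lysolecithin values exceeded 2.14, the highest NaCl value. They lay between 3.78 and 5.73, while 30 other lysolecithin values and 34 NaCl values piled up from 1.93 to 2.14, and 0 values lay between the pile-up and the 5. Strong hybridisation on a scale without a ceiling could not be tested, since the densities behind this table are not analysed here, and so it remains possible.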

How the results depend on the processing

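Local background, the report values and the settings that leave out the 8 genes or the patch, and all those for the unnamed spots, were chosen after seeing the data. The control scaling under blank subtraction, the list medians under the filters on genes and the bounds under each setting were corrected after a first look at their values. Single values were called moved when they differed by over 0.27 on the log2 scale, the SD between repeated control spots, a tolerance also chosen after seeing the data. It is too small for unsaturated spots, since 6 of those 9 spots were near the ceiling, and the shift of 0.27 from setting medians equal lies just inside it, so the counts of single values do not show stability. No paired analysis was possible because each group has 1 array. Scaling by Actb and the value table as a source for named genes were not run, since neither was matched to the workbook's array.

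Against 3 lower genes in the main setting, there were 11 with medians set equal, 6 with sums set equal, 1 with Gapdh alone, 6 with Ppia alone, 1 without background subtraction, 5 with the blank mean subtracted and 14 with local background subtracted. The count with the blank mean is out of 22 genes, and the others are out of 49. With no filter 51 genes were higher and 46 lower, and among genes above the median level 22 and 18; these settings admit genes called absent. Without the 8 genes 3 were higher instead of 6. The growth factor list median of 1.02 became 0.67 without background subtraction, 2.61 with local background, 0.11 with no filter and 0.73 above the median level. The GDNF list median of 0.17 became -0.25 with no filter (-0.25 above the median level). The share present, taken as density above 1.5 times the blank median, was 6.46% (NaCl) and 6.84% (lysolecithin). Among unnamed spots of at least 0.5 on 1 array, 21 were higher and 7 lower, against 33 and 16. With local background subtracted, Dlg4 reversed to -0.027, close to no change, and Dcamkl1 to -0.81. The changes behind both were within the SD of 2317 units, so neither shows a direction. Of 226 single-gene values under alternatives, 193 stayed within the tolerance, 31 moved and 2 reversed, where reversed is a sign change of a value past 1.5-fold. Values within 1.5-fold, such as Bdnf and Ntf5, changed sign without being counted. Many of the 193 could not move past the tolerance. Settings that only leave out spots or genes kept the main values of the rest, and each rescaling shifted all values by 1 amount of at most 0.27. With the blank mean subtracted most named genes gave no value. Apart from the construction of the filters, the cause was not tested. The blanks lie beside saturated spots and do not measure signal over background elsewhere.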

Other observations

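The test in this part was chosen after the result was seen. Across the 288 spots, the log2 ratio of spot density and that of the local background had a Pearson r of 0.81 and a Spearman rho of 0.78; spots are not independent replicates. Log2 ratios of adjacent spots on the grid had a correlation of 0.40, and the highest value in 10000 random placements of the same ratios was 0.18.

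In the unnamed value table the values of both arrays had a Pearson r of 0.73 and a Spearman rho of 0.89 across 128 spots.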
